A study of Bos taurus with 8 samples.

How the data were processed

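Gene expression was measured in BOMA cells with 8 Agilent two-colour bovine arrays of 45220 spots, 1417 of them controls. Per the labels, RNA of untreated cells was labelled with Cy3 and RNA of cells stimulated with FhWey-ES or FhWild-ES (10 µg/ml, 24 h) with Cy5, with 4 arrays per preparation. The authors scanned the arrays and quantified them with Agilent Feature Extraction; per the file headers the version was 10.10.1.1, while the submitters' processing notes name 10.7.3.1. Per the file headers the scanner columns hold intensity, as the mean brightness of each spot and the median of its local background in each channel, with no background subtracted. Further deposited columns hold intensity after background subtraction, detrending and dye normalization by the software, log10 ratios of Cy5 over Cy3 made from them, and other columns of flags with values 0 or 1. The deposited series matrix holds log10 ratios equal to the log10 ratio column of the scanner output (largest difference 0). Of its values, 80.0% to 87.5% equal the log10 of the processed signals' ratio within 1e-04, and almost all others are 0.

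Scanned intensities were used for all main results. Background was corrected with normexp (offset 50). Then log2 ratios of Cy5 over Cy3 were normalized within each array by loess with control spots at weight 0. Spots marked as outliers by the software were left out (5 to 24 gene spots per array), and duplicate spots were averaged. A probe was kept when it was well above background on at least 3 of the 4 arrays of 1 group in 1 channel, which left 30839 of 43653 probes. Between 60.5% and 70.5% of gene spots per array were well above background in Cy3 and 63.2% to 72.5% in Cy5; the number of arrays limits the precision. Probes were named through a table of RefSeq genes of the assembly ARS-UCD2.0, used for names only. Of these, 26743 were matched by RefSeq accession, 1814 by another accession, 5115 by the symbol in the annotation and 138 by an older symbol. In all 33810 were matched, with 9843 not matched and kept under their own identifiers. The brightest of a gene's probes over all arrays represented it, 7675 genes having more than 1. This gave 17630 genes or transcripts, 13 of whose log ratios were missing; 17617 had values on all arrays.

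Log2 ratios of all 8 arrays were fitted with limma 3.58.1 in R 4.3.3 (with data.table in version 1.17.8), with a mean per preparation and default empirical Bayes. Two-sided tests were made of each mean against 0 and of their difference, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Because all arrays share 1 estimate of the spread, an array of one preparation affects calls of the other. Lists of genes with at least 5 tested members, 36 in all, were tested with camera (preset correlation 0.01), adjusted over the lists of each contrast, beside camera with an estimated correlation and fry. A list's direction is that of camera, relative to all other genes. The lists, the model, the threshold, the alternatives and the choice of named genes were fixed before the data were examined. Named genes are, per preparation, the 12 largest increases and 12 largest decreases among genes with a symbol that passed and had the same sign on 4 of 4 arrays. For the difference they are the 10 largest each way. Added were up to 4 members per list and contrast with the smallest p and any member of the lists of inflammatory mediators and alternative activation. COX3, the sets of mitochondrial transcripts and the sets of shared-sequence genes were chosen after their values were seen. The overlap of the preparations was set beside that of independent lists and beside 100 simulations in which no gene responded and all control wells were shared.

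Probe sequences were matched to each other with BLAST 2.17.0 (word size 11, E value 0.001). A probe was called shared-sequence when it matched probes of at least 3 other genes or held at least 5 TG or CA units in a row, which applied to 811 of 43653 probes and to 229 of the tested genes. Alternatives fixed in advance were the software's processed signals, no background correction, an offset of 16, median centring in place of loess, and scale normalization between arrays. Others were no filter and a stricter filter, the mean of a gene's probes, outlier spots kept, empirical Bayes with trend and robust, array weights, and a minimum of 2-fold. Further ones were a threshold of 0.01, the replicate number as a block, the series matrix values, each array left out in turn, each preparation's own 4 arrays, both other list tests and separate-channel analysis (intraspot correlation 0.335). Alternatives added after the data were seen were the removal of shared-sequence probes, a correction for probe G and C content, leaving out both arrays whose ratios fell with G and C content, and median centring over the probes past the filter.

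The pipeline was tested on simulated data with 17630 genes and 200 changed genes in 10 runs. For FhWey-ES against untreated it recovered 14.2% of 1.1-fold, 98.8% of 1.25-fold, 100% of 1.5-fold and 100% of 2-fold changes, with 6.51% of calls false. For the difference between preparations it recovered 3.4%, 74.2%, 100% and 100%, with 6.97% false. A simulated shift of the lysosomal list by a log2 ratio of -0.1 over 17617 genes was called in 20 of 20 runs. These simulations drew genes independently of each other, with equal spread on all arrays and no dye bias. The rates therefore need not hold in the data, where genes may be correlated and array scales differed. Slide and scan day coincide with the preparation, so they could not be fitted.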

Results

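The series compared BOMA cells, a bovine macrophage line, with and without excretory-secretory products of the liver fluke Fasciola hepatica. One preparation, FhWey-ES, and another, FhWild-ES, were each applied at 10 µg/ml for 24 h; the series title speaks of wild and laboratory isolates. Each of the 8 two-colour bovine arrays set RNA of a stimulated well in Cy5 against RNA of an untreated well in Cy3, with 4 arrays per preparation and no dye swap. Values of the first and second comparison are mean log2 ratios of stimulated over untreated over 4 arrays, and values of the third are differences between these means. The ± values are standard errors of the model, whose spread is pooled over all 8 arrays, and adjusted p comes from limma. The p-values measure only the spread between these arrays, which the sample descriptions call technical replicates and the design text calls separate wells. Between 60.5% and 70.5% of gene spots in Cy3 and 63.2% to 72.5% in Cy5 were well above background, and 0 were saturated. In all, 17630 genes or transcripts were tested, 12093 of them with a gene symbol. Across genes, arrays of FhWey-ES correlated with each other at 0.450 to 0.751, arrays of FhWild-ES at 0.183 to 0.530, and arrays of different preparations at 0.0787 to 0.596. The number of arrays limits the precision of every value. Each preparation was hybridised on its own slide and scanned on its own day, so slide, day and preparation cannot be told apart.

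The first comparison asks which RNAs of the macrophages differed between FhWey-ES and untreated samples. Without a dye swap, dye bias of single genes cannot be told from stimulation in any call of this comparison or the second. RNA of the immediate-early gene EGR1 increased 1.34-fold (log2 ratio 0.43 ± 0.046, adjusted p = 5.5e-05). FOS rose by a log2 ratio of 0.32 ± 0.050 and NFKBIA, the inhibitor of NF-kappa B, 1.26-fold (0.34 ± 0.041). RIGI, a sensor of viral RNA, rose 1.29-fold (0.37 ± 0.043), with 1 of 2 probes up. The signal transducer SMAD4 rose 1.36-fold (0.44 ± 0.053), the apoptosis inhibitor XIAP 1.31-fold (0.39 ± 0.066) and the adhesion molecule ALCAM 1.29-fold (0.36 ± 0.052). The chemokine CCL5 fell by 0.40 ± 0.072 on the log2 scale (adjusted p = 0.0018), the largest decrease of a gene with a symbol, on 3 of 3 probes. MYC fell by 0.21 ± 0.040, the protease inhibitor PI3 to a log2 ratio of -0.32 ± 0.061, and the metalloprotease ADAM8 to -0.35 ± 0.067. The glycosyltransferase LARGE2 fell by 0.40 ± 0.070, with 1 of 2 probes down. All of these moved the same way on 4 of 4 arrays. In total 3013 genes rose and 1233 fell, 4246 calls of which 71.0% were increases. Changes were small: the median called gene changed 1.14-fold, 16 genes changed at least 1.5-fold and 0 at least 2-fold, while 6778 genes had an unadjusted p under 0.05. The largest increases included an 18S ribosomal RNA sequence, RN18S1, at 1.89-fold (0.92 ± 0.095; 3 of 3 probes), which the files name as an inositol trisphosphate receptor. INHBC rose 1.60-fold (0.68 ± 0.098), CAMK1G 1.59-fold (0.67 ± 0.10), TMEM201 1.54-fold (0.62 ± 0.089; the median of its 3 probes was 0.085) and the mitochondrial ND4L 1.49-fold (0.58 ± 0.089). INHBC, CAMK1G, TMEM201 and, less closely, ND4L varied between arrays alongside RN18S1, and whether their probes read ribosomal RNA was not tested. PTPRC (CD45; 1.67-fold), TYK2 (1.63-fold), ATOSB (1.57-fold) and AGTR1 (1.48-fold) also rose, but through shared-sequence probes, which match probes of at least 3 other genes or hold runs of TG or CA. At their other probes PTPRC rose by 0.16 (adjusted p = 0.024), TYK2 was at 0.0041 (0.96) and ATOSB turned to -0.069 (0.19). Without FhWey-ES replicate 1 there were 2289 calls, 2782 without replicate 3 and 1607 without replicate 4. After scale normalization between arrays 95 genes passed, 87.4% of them increases. With median centring in place of loess 12793 passed, 80.1% increases, and centred on the probes past the filter 10259, 54.8% increases.

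**Figure D1:**
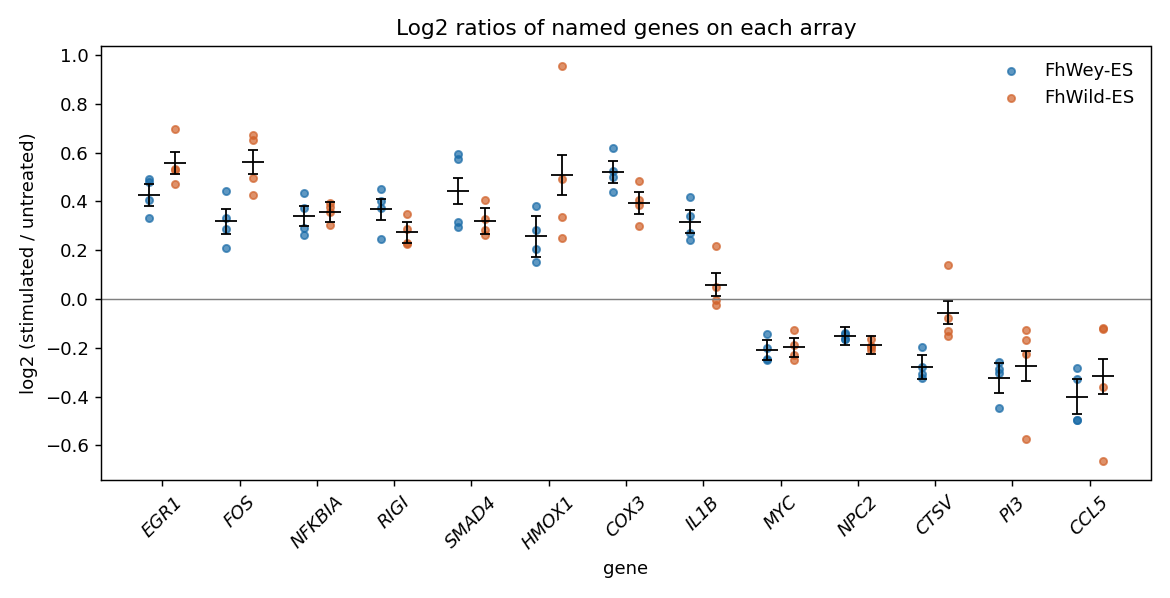
Log2 ratio of stimulated over untreated cells (y axis) for named genes (x axis) on each of the 4 arrays per preparation (points), with the mean (dash) and its standard error from the model (bars). EGR1 averages 0.43 with FhWey-ES and 0.56 with FhWild-ES, and CCL5 -0.40 and -0.32 (COX3 was chosen after its values were seen; with median centring in place of loess NPC2 and CTSV lie above the median of all genes).

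Among the functions listed before the data were examined, the lysosomal protease list held decreases with FhWey-ES. Of its 31 tested members, 0 higher and 10 lower were called (0 and 11 adjusted over the list alone). The median log2 ratio was -0.10 and the set test gave adjusted p = 8.4e-05 (adjusted p = 0.44 with an estimated correlation). The cathepsin CTSV fell by 0.28 ± 0.049 (5 of 5 probes down), legumain, LGMN, to a log2 ratio of -0.19 ± 0.042 and the cholesterol carrier NPC2 to -0.15 ± 0.037. With median centring in place of loess the median of all tested genes rose to 0.37, and the list lay 0.059 above it, CTSV 0.10 and NPC2 0.022 above it. The direction of the list thus differed between normalizations, and whether the intensity trend of each array is the reason was not tested. Under median centring MYC (-0.093), CCL5 (-0.32) and PI3 (-0.11) stayed lower relative to all genes. Of the inflammatory cytokines and mediators, 6 higher and 1 lower of 18 tested (7 and 1 adjusted over the list alone) were called, with a set test adjusted p of 0.40. IL1B rose by a log2 ratio of 0.32 ± 0.047 (adjusted p = 5.3e-04) at its brightest probe, but its other 2 probes did not rise and the mean of its probes did not pass. CCL3 rose 1.15-fold (0.20 ± 0.051), a call lost without FhWey-ES replicate 4 (adjusted p = 0.097). With median centring CCL3 (-0.035), IRF4 (-0.14) and IL10 (-0.080) lay below the median of all genes. OSM was above background on 0 of 4 untreated (Cy3) and 4 of 4 stimulated (Cy5) samples. With its untreated level set no lower than the dimmest signal above background, the estimated rise was 1.06-fold (adjusted p = 0.031 from the model without this floor). CXCL3, also among the genes called higher, was above background on 0 of 4 untreated and 1 of 4 stimulated samples. With the same floor its estimated rise was 1.07-fold (adjusted p = 0.0061 from the model without it). On each of these 4 arrays more spots were above background in Cy5 than in Cy3, so channel and stimulation cannot be told apart in these counts. Markers of alternative activation split. ARG1 rose 1.21-fold (0.28 ± 0.051; shared-sequence probe) and IRF4 1.13-fold (0.18 ± 0.048). IL4R fell by 0.26 ± 0.051 (4 of 4 probes) and VEGFA to a log2 ratio of -0.24 ± 0.057 (3 of 3). The list counted 2 higher and 5 lower of 23 (2 and 5 adjusted over the list alone). Without FhWey-ES replicate 4, IRF4 (adjusted p = 0.12), VEGFA (0.060) and LGMN (0.052) lost their calls. IL10 at 0.12 ± 0.046 (adjusted p = 0.080) and NOS2 at 0.13 ± 0.062 (0.12) did not pass. Without FhWild-ES replicate 2, which lends its spread to the test, both did (0.0496 and 0.047), and NOS2 did without FhWey-ES replicate 3 (0.043). Complement factor CFB fell by 0.25 ± 0.041, osteopontin, SPP1, to a log2 ratio of -0.25 ± 0.051, while thioredoxin reductase, TXNRD1, rose 1.15-fold (0.21 ± 0.041).

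The second comparison puts FhWild-ES against untreated cells, with the same limit from dye bias. FOS rose 1.48-fold (log2 ratio 0.56 ± 0.050, adjusted p = 5.8e-05) and EGR1 1.47-fold (log2 ratio 0.56 ± 0.046, adjusted p = 2.9e-05), in each case on 4 of 4 arrays. NFKBIA rose 1.28-fold (0.36 ± 0.041), RIGI 1.21-fold (0.27 ± 0.043) and SMAD4 by a log2 ratio of 0.32 ± 0.053. Heme oxygenase, HMOX1, rose 1.42-fold (0.51 ± 0.082, adjusted p = 0.0032), metallothionein, MT2A, 1.24-fold (0.31 ± 0.047) and the glutathione synthesis gene GCLM 1.17-fold (0.23 ± 0.041). The chaperone HSPA8 rose 1.20-fold (0.26 ± 0.048; 6 of 6 probes) and thymosin beta, TMSB4X, 1.38-fold (0.47 ± 0.045; 3 of 3). Gamma actin, ACTG1, rose 1.33-fold (0.41 ± 0.057; 6 of 6), and the glycolytic ENO1 1.41-fold (0.50 ± 0.049; 5 of 5). CCL5 fell by 0.32 ± 0.072 on the log2 scale (adjusted p = 0.020). UBXN1 fell to a log2 ratio of -0.34 ± 0.047, the lysosomal sorting receptor IGF2R to -0.33 ± 0.071 and MYC to -0.20 ± 0.040 (1 of 2 probes). In total 646 genes rose and 341 fell, 987 calls of which 65.5% were increases, 1 of them at least 1.5-fold and 0 at least 2-fold; 4123 genes had an unadjusted p under 0.05. RN18S1 rose 1.61-fold (0.69 ± 0.095). The increases of PTPRC (0.49 ± 0.052), TYK2 (0.48 ± 0.047) and ATOSB (0.55 ± 0.045) came through shared-sequence probes and did not pass at their other probes (adjusted p = 0.81, 0.80 and 0.97). Without FhWild-ES replicate 2 there were 473 calls, and CCL5 (0.069) and IGF2R (0.062) did not pass. Without replicate 3 there were 313, and MYC (0.078) and IGF2R (0.090) did not. Without replicate 4 there were 452, and CCL5 (0.066) did not. After scale normalization 0 genes passed (4727 with an unadjusted p under 0.05). Without background correction 2511 passed, 54.1% of them increases. With median centring it was 12632, 80.8% increases, and centred on the probes past the filter 10123, 51.6% increases.

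With FhWild-ES, the list of ribosomal proteins passed the set test with the preset correlation, toward higher values (adjusted p = 8.9e-04), but not with an estimated correlation (adjusted p = 0.75). Of 75 tested, 18 higher and 0 lower were called (22 and 1 adjusted over the list alone), and the median was 0.052. RPS27A rose 1.28-fold (0.36 ± 0.044), RPS20 1.24-fold (0.31 ± 0.041) and RPL31 1.20-fold (0.26 ± 0.041; 6 of 6 probes). On the scanner software's processed signals the median of the list turned to -0.0057 and the set test did not pass (adjusted p = 0.83). With the mean of each gene's probes it did not pass either (median 0.032, adjusted p = 0.22). With median centring in place of loess the set test gave adjusted p = 1.7e-06. The list then lay 0.51 above the median of all genes, against 0.046 with loess. The size of its shift thus differed between normalizations, and whether the intensity trend of each array is the reason was not tested. With FhWey-ES the same list counted 22 higher and 3 lower (24 and 4 adjusted over the list alone) and did not pass the set test (adjusted p = 0.36). The lysosomal protease list was lower with FhWild-ES too: 0 higher and 5 lower (0 and 7 adjusted over the list alone), median -0.053, adjusted p = 0.0099 (adjusted p = 0.75 with an estimated correlation). NPC2 fell by 0.19 ± 0.037 and cathepsin A, CTSA, to a log2 ratio of -0.25 ± 0.055. CTSA was not called without FhWild-ES replicate 2 (adjusted p = 0.072) or replicate 3 (0.094). The list's call was lost without FhWild-ES replicate 3 (adjusted p = 0.055) or replicate 4 (0.12). With the mean of each gene's probes its median was -0.0084 and the call was lost (adjusted p = 0.37). With median centring, where the median of all genes was 0.36, the list lay 0.10 above it. Centred on the probes past the filter, it passed the set test toward higher values (adjusted p = 0.027).

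Many genes were called with both preparations, and as all arrays have the same dye orientation, dye bias is not excluded as a cause. Of these genes, 459 rose and 170 fell, against 110 and 23.8 for independent lists of these sizes, and 0 moved in opposite directions, against 103. They included EGR1, FOS, NFKBIA, RIGI, SMAD4, MYC, NPC2, CCL5 and ENO1 (2 of 5 probes up with FhWey-ES). With median centring in place of loess NPC2 lay 0.022 and 0.0077 above the median of all genes, while MYC and CCL5 stayed below it. Of the 987 genes called with FhWild-ES, 63.7% were also called with FhWey-ES, and 96.5% had the same sign there. A simulation in which both groups shared every control well and no gene responded gave 0 such genes in all 100 runs, which does not show how much shared wells add when genes respond. Across genes, mean log2 ratios of the preparations correlated with Pearson's r = 0.50 and Spearman's rho = 0.477, where genes are not independent replicates. The simulation gave 0.501 and 0.481, so r is not informative here, while its covariance, 0.0012, was below the observed 0.0058. Whether the preparations shared control wells is not stated. Without FhWild-ES replicate 2 there were 405 shared calls, 232 without FhWild-ES replicate 3, 336 without FhWild-ES replicate 4 and 348 without FhWey-ES replicate 4. A further 3617 genes were called with FhWey-ES only and 358 with FhWild-ES only, but the difference itself passed for 152 and 2 of them.

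**Figure D2:**
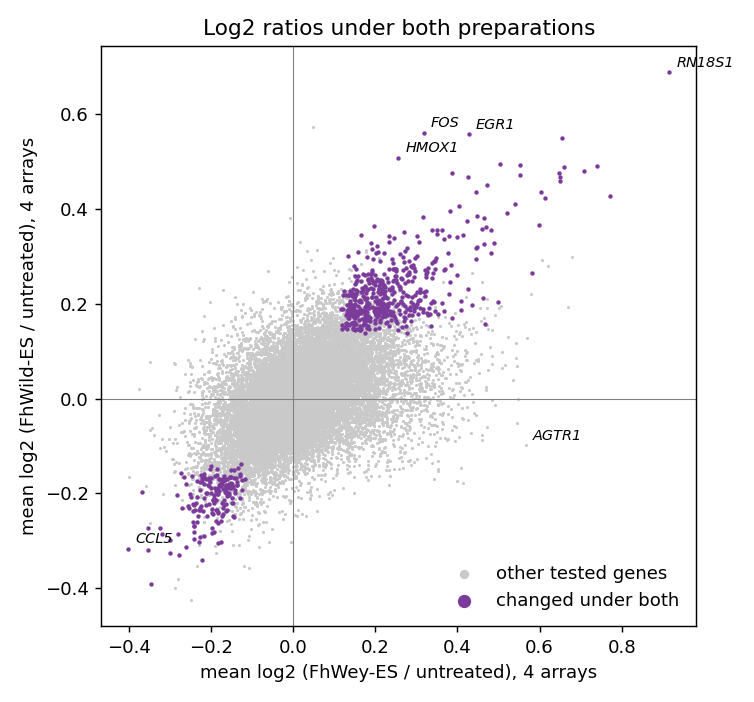
Mean log2 ratio of stimulated over untreated cells with FhWey-ES (x axis) and with FhWild-ES (y axis), each over 4 arrays. Each point is one of the 17630 tested genes or transcripts, and purple points mark those called with both, 459 higher and 170 lower.

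The third comparison asks where the preparations differed, as FhWey-ES minus FhWild-ES. With FhWey-ES TLR2 was higher by 0.45 ± 0.085 (adjusted p = 0.039), TLR6 by 0.34 ± 0.070 (0.044), and lysozyme, LYZ, by 0.46 ± 0.083 (0.038). So were the RNA-activated kinase EIF2AK2 by 0.40 ± 0.077 (0.039) and the kinase adaptor TAB2 by 0.41 ± 0.088 (0.046). The largest difference of a named gene was AGTR1, the angiotensin receptor, at 0.66 ± 0.077 (0.0059; 4 of 4 probes). PLAAT1 (0.60 ± 0.080), ACOT11 (0.59 ± 0.081; 7 of 7 probes) and AFF4 (0.55 ± 0.086) were higher as well. TGFB2 (0.32 ± 0.062), ARG1 (0.33 ± 0.073), APAF1 (0.31 ± 0.068) and the proteasome subunit PSMD11 (0.26 ± 0.057) were higher too. TLE5 (-0.43 ± 0.093; 1 of 2 probes), AP2A1 (-0.36 ± 0.081) and POLR1C (-0.34 ± 0.073) were lower. In total 151 genes were higher and 4 lower, and 2766 had an unadjusted p under 0.05. AGTR1, PLAAT1, ACOT11, ARG1 and TLR2 were read through shared-sequence probes, as were 45 of the 151 genes called higher against 184 of the 17475 not called; this set was chosen after its values were seen, and probes that match each other are not independent. At an unshared probe ACOT11 was still called (0.53, adjusted p = 0.044), and AGTR1, PLAAT1, ARG1 and TLR2 had none. Without shared-sequence probes 7 genes passed over 17490 tested, 6 of them among the 155. Of the 106 genes called higher through other probes 5 stayed. The rest kept their probe and ratios but did not pass after the refit and its adjustment over all genes. With either median centring, scale normalization, the software's processed signals or the mean of a gene's probes, 0 genes passed (517, 676, 1667, 2519 and 2648 with an unadjusted p under 0.05). The count was 1 without FhWey-ES replicate 1, 311 without replicate 2, 0 without replicate 3 (2651 with an unadjusted p under 0.05) and 0 without replicate 4 (1839). It was 1, 101 and 8 without FhWild-ES replicate 1, 2 or 4. AGTR1 lost its call without FhWey-ES replicate 3 (adjusted p = 0.065) or 4 (0.058). Every other named gene lost it without FhWey-ES replicate 1, 3 or 4 or FhWild-ES replicate 1 (adjusted p = 0.063 to 0.21). All but PLAAT1, ACOT11 and AFF4 of these lost it without FhWild-ES replicate 4 (0.066 to 0.088). TAB2, APAF1, PSMD11, TLE5, AP2A1 and POLR1C also lost it without FhWild-ES replicate 2 or 3 (0.059 to 0.12), and TLR6 without replicate 2 (0.061). The difference did not pass for IL1B, at 0.26 ± 0.067 (adjusted p = 0.086), for FOS, at -0.24 ± 0.071 (0.12), or for EGR1, at -0.13 ± 0.064 (0.34). Among the lists, oxidative phosphorylation was lower with FhWey-ES than with FhWild-ES, at a median of -0.044 over 55 tested members, -0.013 without FhWild-ES replicate 4 and -0.024 without FhWey-ES replicate 1. The set test gave adjusted p = 0.0095 (adjusted p = 0.86 with an estimated correlation, and 0.076 without FhWild-ES replicate 4). There were 0 members called (0 adjusted over the list alone), and its member NDUFS1 was at -0.19 ± 0.069 (0.21; 5 of 5 probes).

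Of 36 lists, the set test called 1 with FhWey-ES, 2 with FhWild-ES and 1 in the difference, and 0 with an estimated correlation. A self-contained rotation test, fry, which asks whether members move on balance one way, called 11, 0 and 0. Lists past fry but not the set test with FhWey-ES were JAK-STAT and SOCS signalling (5 higher and 0 lower of 21, 5 and 0 adjusted over the list alone), inflammatory cytokines and mediators, lipid metabolism and efflux (5 higher and 1 lower of 25, 6 and 1 adjusted over the list alone) and inflammasome and pyroptosis (2 higher and 0 lower of 7, 2 and 1 adjusted over the list alone). Others were cytokine and chemokine receptors (6 higher and 1 lower of 22, 6 and 2 adjusted over the list alone), TGF-beta and SMAD signalling (8 higher and 2 lower of 26, 8 and 4 adjusted over the list alone) and markers of macrophages (3 higher and 0 lower of 12, 3 and 0 adjusted over the list alone), B cells (2 higher and 0 lower of 5, 2 and 0 adjusted over the list alone), endothelium (0 higher and 0 lower of 5, 0 and 0 adjusted over the list alone) and dendritic cells (2 higher and 0 lower of 8, 2 and 0 adjusted over the list alone). These counts include TYK2 in JAK-STAT signalling, PTPRC among macrophage markers, and 1 gene each of the B cell markers and cytokine receptors, all read through shared-sequence probes. At its other probe TYK2 was not called (0.0041, adjusted p = 0.96), and fry was not run without these probes. In the other lists the genes called higher and lower are given next. Over all 17630 genes, 3013 and 1233 were called with FhWey-ES, and 646 and 341 with FhWild-ES. Against untreated cells these other lists did not pass the set test, which compares a list with all other genes. Their counts are therefore no sign of a response particular to a list. Toll-like receptor and NF-kappa B signalling had 5 and 3 of 35 with FhWey-ES (5 and 3 adjusted over the list alone) and 1 and 1 with FhWild-ES (1 and 1). MAP kinase and immediate-early genes had 6 and 2 of 24 with FhWey-ES (8 and 2 adjusted over the list alone) and 2 and 1 with FhWild-ES (5 and 1). The interferon response had 5 and 3 of 30 with FhWey-ES (5 and 3 adjusted over the list alone) and 2 and 0 with FhWild-ES (3 and 1). The oxidative stress response had 6 and 6 of 34 with FhWey-ES (7 and 6 adjusted over the list alone) and 7 and 0 with FhWild-ES (10 and 4). Heat shock genes had 3 and 0 of 23 with FhWey-ES (1 and 0 adjusted over the list alone) and 3 and 0 with FhWild-ES (6 and 0). Endoplasmic reticulum stress had 3 and 3 of 28 with FhWey-ES (3 and 3 adjusted over the list alone) and 3 and 2 with FhWild-ES (3 and 3). Apoptosis had 6 and 4 of 33 with FhWey-ES (7 and 4 adjusted over the list alone) and 0 and 1 with FhWild-ES (2 and 1). Glycolysis and hypoxia had 7 and 4 of 31 with FhWey-ES (8 and 5 adjusted over the list alone) and 5 and 0 with FhWild-ES (5 and 3). Cholesterol biosynthesis had 1 and 2 of 24 with FhWey-ES (1 and 1 adjusted over the list alone) and 2 and 0 with FhWild-ES (2 and 1).

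Oxidative phosphorylation had 4 and 6 of 55 with FhWey-ES (4 and 5 adjusted over the list alone) and 6 and 1 with FhWild-ES (6 and 1). The actin cytoskeleton had 6 and 4 of 29 with FhWey-ES (7 and 5 adjusted over the list alone) and 4 and 0 with FhWild-ES (5 and 2). The proteasome had 3 and 3 of 31 with FhWey-ES (3 and 3 adjusted over the list alone) and 2 and 1 with FhWild-ES (2 and 1). RNA splicing had 6 and 0 of 31 with FhWey-ES (6 and 0 adjusted over the list alone) and 1 and 1 with FhWild-ES (4 and 2). The cell cycle had 7 and 1 of 39 with FhWey-ES (6 and 1 adjusted over the list alone) and 3 and 1 with FhWild-ES (7 and 1). Antigen presentation had 4 and 3 of 24 with FhWey-ES (4 and 3 adjusted over the list alone) and 2 and 0 with FhWild-ES (3 and 1). Matrix remodelling had 1 and 3 of 22 with FhWey-ES (1 and 3 adjusted over the list alone) and 0 and 3 with FhWild-ES (0 and 3). Integrins and adhesion had 2 and 3 of 16 with FhWey-ES (2 and 3 adjusted over the list alone) and 0 and 0 with FhWild-ES (0 and 0). Complement and coagulation had 0 and 1 of 18 with FhWey-ES (0 and 1 adjusted over the list alone) and 0 and 1 with FhWild-ES (0 and 1). Autophagy had 1 and 5 of 23 with FhWey-ES (1 and 5 adjusted over the list alone) and 1 and 3 with FhWild-ES (1 and 4). In these lists the mean and the median differed in sign with FhWey-ES for Toll-like receptor signalling, integrins, cholesterol biosynthesis, endoplasmic reticulum stress, oxidative stress and autophagy, and with FhWild-ES for glycolysis and hypoxia, so members went both ways. For the cell cycle and for glycolysis and hypoxia with FhWey-ES, median and mean were above 0 while the set test, relative to all genes, pointed down. Positions of probes on the cow genome build UMD_3.1, as the arrays' annotation gives them, are chromosome 7, 51442425 to 51442484 for EGR1, chromosome 10, 86887064 to 86887123 for FOS and chromosome 21, 46065591 to 46065650 for NFKBIA. They are chromosome 19, 14831074 to 14831130 for CCL5, chromosome 8, 84976471 to 84976530 for CTSV and chromosome 17, 3950552 to 3950611 for TLR2.

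**Figure D3:**
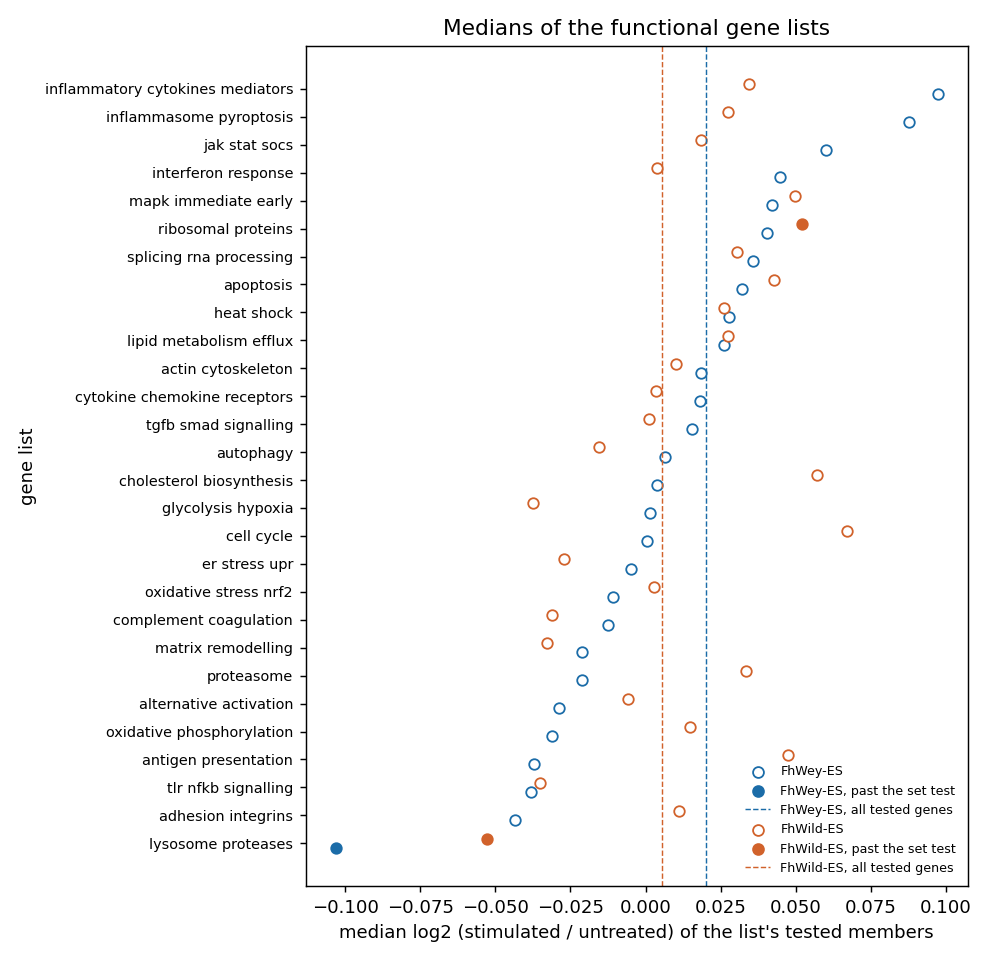
Median log2 ratio of stimulated over untreated cells (x axis) of the tested members of each functional list (y axis), with filled points for lists past the set test and dashed lines at the medians of all tested genes, 0.020 with FhWey-ES and 0.0056 with FhWild-ES. The lysosomal proteases lie at -0.10 and -0.053, and lie above the median of all genes with median centring in place of loess.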

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

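The tests that count slides with both preparations and arrays with swapped dyes were chosen after the result was seen. The test of other probes for genes without shared sequence was chosen after 5 of those 106 genes were seen to stay past the threshold without shared-sequence probes. The other tests were written after the patterns were seen but before their own values were.

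Some arrays lay far from the other 3 of their group. PTPRC was at 0.43 on FhWild-ES replicate 4 against 0.51 on the others. ADAM8 was at -0.14 on FhWey-ES replicate 2, LARGE2 at -0.46 on FhWild-ES replicate 2, RPS20 at 0.37 on FhWey-ES replicate 3 and TLE5 at -0.69 on FhWey-ES replicate 3. The standard deviation of log2 ratios was 0.0963 on FhWey-ES replicate 2, against at least 0.165 on the others of its group. The spike-in slope was 0.870 on FhWild-ES replicate 4, against 0.859 to 0.860. By the Dixon ratio of gap to range, chance gives about 1 in 20 groups, and 138 groups were checked. The outliers listed here are about as many as that rate gives, so chance can account for their number.

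These genes differed between the preparations by a test of the difference, as FhWey-ES minus FhWild-ES. They were AGTR1 by 0.66, PLAAT1 by 0.60, ACOT11 by 0.59, AFF4 by 0.55, LYZ by 0.46. Smaller differences were TLR2 by 0.45, TAB2 by 0.41, EIF2AK2 by 0.40, TLR6 by 0.34, ARG1 by 0.33, TGFB2 by 0.32, APAF1 by 0.31 and PSMD11 by 0.26. In the other direction they were TLE5 by -0.43, AP2A1 by -0.36 and POLR1C by -0.34. The first pattern is that 151 of the 155 differences were higher with FhWey-ES, 45 of them read through shared-sequence probes. For 24 of these 45 genes with other probes, the median difference there was 0.0386 (95% interval -0.0279 to 0.131; 15 above 0) against 0.454 at the called probes. Genes were chosen by the called probe, which by itself lowers the value at other probes. As genes without shared sequence also fell at theirs, the drop does not single out signal from repeated sequence, which stays an untested candidate. ACOT11 was also called at an unshared probe (adjusted p = 0.044). Unshared probes matched probes of fewer than 3 other genes and held no such TG or CA run, so repeated sequence is not excluded there. For 74 of the other 106 genes the median at other probes was 0.0904 (0.0567 to 0.138; 62 above 0) against 0.364, so most of the difference may lie at the called probe. Choosing genes by that probe and dimmer other probes also lower this value, and a smaller difference is shared. Of the 35 splits of the 8 arrays 1, the real one, gave as many genes (155, highest other 0). This split is also that of slide and scan day. It argues against chance only for some difference between the arrays of one slide and those of the other. It does not bear on single genes, and the count depended on single arrays, as given above. Slide and scan day cannot be told from the preparation, since 0 slides hold both, and the isolates themselves stay open as an untested biological explanation.

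The second pattern is the 629 genes that moved the same way with both preparations. Of 100 drawn sign patterns 1, the real one, gave as many (highest other 0). Where arrays agree, flipping some of them widens the spread, and flipping a whole preparation gives 0 by the definition of the count. The outcome shows only that ratios agreed in sign across arrays, which any effect common to all arrays, dye bias included, would give. Dye bias common to all arrays, as the whole cause, requires equal effects. The error-corrected correlation between preparations was 0.678 (jackknife standard error 0.191, range without single arrays 0.598 to 0.850). It lay less than 2 standard errors under the bound of 0.9, so a dye bias common to all arrays is not excluded. A dye bias that differs between slides need not reach this bound and was not tested. The correlation assumes independent errors between preparations, and shared control wells would raise it. As part of the cause dye bias cannot be told from stimulation, because 0 arrays carry the untreated RNA in Cy5. A response shared by both preparations may therefore stand beside dye bias, and neither was separated. For each preparation alone, only 8 sign patterns exist, too few for a share under 0.05. The real pattern gave 4246 genes with FhWey-ES (highest other 0) and 987 with FhWild-ES (highest other 0), each the only 1 as large.

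The third pattern is the lysosomal protease list, lower with both preparations by the set test with the preset correlation. With an estimated correlation neither call held (adjusted p = 0.44 and 0.75), and the call with FhWild-ES was lost without FhWild-ES replicate 3 (0.055) or 4 (0.12). A correction for probe G and C content left its median at -0.109 from -0.103 with FhWey-ES and at -0.059 from -0.053 with FhWild-ES, a ratio of at least 1.06, which argues against G and C content as the cause. Normalization stays open: with median centring in place of loess the list lay 0.059 and 0.10 above the median of all genes (list medians 0.43 and 0.47). Centred on the probes past the filter, the list passed the set test toward higher values with FhWild-ES (adjusted p = 0.027). Thus the decrease may depend on how the intensity trend of each array is removed. Regroupings of arrays also gave as many lists, in 5 of 8 sign patterns with FhWey-ES (1 list, highest other 5) and 7 of 8 with FhWild-ES (2, highest other 7), where 8 patterns are too few for a share under 0.05. For the difference 28 of 35 splits did (1, highest other 10), so chance is not excluded there. Uptake or secretion changes of the cells were not tested.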

How the results depend on the processing

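The alternatives without shared-sequence probes, with a correction for G and C content, with both G and C dependent arrays left out and with centring over the probes past the filter were chosen after the data were seen. The others were planned. Leaving out 1 array at a time, calls ranged from 1607 to 5751 for FhWey-ES, 313 to 1093 for FhWild-ES, 0 to 311 for the difference and 232 to 508 for shared calls. Lists ranged from 1 to 2, 1 to 3 and 0 to 5, and r from 0.430 to 0.586. Calls for FhWey-ES against untreated stayed within 1.5 times 4246 except under median centring (12793, over filtered probes 10259), scale normalization (95), at least 2-fold (0; 6778 with an unadjusted p under 0.05), a threshold of 0.01 (1690) and without single arrays as above. The other moved values, as FhWild-ES calls, calls in the difference and shared calls, follow. Without background correction they were 2511, 567 and 1561. With an offset of 16 they were 399, 1 and 293. With median centring they were 12632, 0 (517 with an unadjusted p under 0.05) and 10987, and over filtered probes 10123, 0 (676) and 8237. Scale normalization gave 0 (4727), 0 (1667) and 0. Array scales, as the median absolute deviation of log2 ratios, ran from 0.0343 to 0.180. The mean of all probes gave 342, 0 (2648) and 236. Array weights gave 2398, 412 and 1332, at least 2-fold 0 (4123), 0 (2766) and 0, and a threshold of 0.01 gave 221, 1 and 161. Empirical Bayes with trend and robust gave 572 for FhWild-ES and 325 shared calls, separate channels 1488 for FhWild-ES and 2 in the difference, and FhWild-ES's own 4 arrays 267. Calls in the difference were 0 (2519) on processed signals, 0 (2520) on the series matrix, 7 without shared-sequence probes and 291 with both G and C dependent arrays left out. The correlation between preparations moved to 0.659 on processed signals, 0.658 on the series matrix and 0.932 under both median centrings. Lists called for FhWey-ES, FhWild-ES and the difference were 7, 15 and 0 under median centring. They were 15 and 17 over filtered probes (first 2 contrasts), 0, 0 and 0 with an estimated correlation and 11, 0 and 0 by fry. FhWild-ES lists were 1 on processed signals and 1 on the series matrix, lists in the difference 2 under scale normalization and 9 by the mean of probes, and FhWey-ES lists 5 by the mean of probes. Median centring moved the median of all genes to 0.37 with FhWey-ES and 0.36 with FhWild-ES. It turned with FhWey-ES MYC (0.28), CCL5 (0.053), IL4R (0.12), VEGFA (0.16), CTSV (0.48), LGMN (0.31), NPC2 (0.39), CFB (0.28), SPP1 (0.15), PI3 (0.26) and the lysosomal list (0.43). With FhWild-ES it turned MYC (0.30), CCL5 (0.15), NPC2 (0.37), CTSA (0.38), IGF2R (0.27), UBXN1 (0.28) and the lysosomal list (0.47). Relative to the median of all genes CTSV, NPC2, CTSA and the lysosomal list turned up. IRF4 (-0.14), CCL3 (-0.035) and IL10 (-0.080) turned down with FhWey-ES, and the others here kept their direction. Centred over filtered probes, MYC (0.0029), IRF4 (-0.039), CTSV (0.20), LGMN (0.034), NPC2 (0.12), CFB (0.0065) and the list (0.15) turned with FhWey-ES. So did MYC (0.021), NPC2 (0.094), CTSA (0.098) and the list (0.19) with FhWild-ES. ATOSB with FhWey-ES turned to -0.069 without shared-sequence probes. Among values of single genes and lists, 1911 kept direction and side of the threshold, 373 kept direction and lost the call, 9 gained one and 30 turned. Of the turns, 18 came under median centring and 11 with centring over filtered probes. Directions of single genes are those of the ratio itself, so a shift common to all genes counts as a turn. CCL3 under median centring counts as kept. Under scale normalization 76 of 87 lost their call. With the replicate number as a block 3780, 684, 198 and 449 genes were called. Evidence for pairing by replicate number was mixed: deviations of equal numbers correlated across genes at 0.137, -0.209, 0.0089 and 0.122, best matches in 2 of 4. A slide block and list tests on separate channels were not run, the former because slide and preparation coincide. The causes of these moves were not tested. Signal over background limits dim genes: 60.5% to 72.5% of spots per array and channel were well above it.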

Other observations

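All sets in this part were chosen after their values were seen, except the marker lists, which were fixed before the data were examined.

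Of 37 tested genes or accessions with probes on the mitochondrial genome, 25 were called higher with FhWey-ES (0 lower, median 0.22), 7 with FhWild-ES (0 lower, median 0.086) and 0 in the difference. Among all 17630, 3013 and 646 were called higher. Many of the 37 are accessions of neighbouring or overlapping sequence, so they are not separate transcripts, and no set test was run. COX3, chosen after its values were seen, was at 0.52 ± 0.044 with FhWey-ES and 0.39 ± 0.044 with FhWild-ES at its brightest probe, with a median over its 3 probes of 0.093 and 0.094.

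Shared-sequence genes were split by the kind of sequence, without a test between the sets. Of 59 genes read through a probe with a run of TG or CA units, 41 were called higher with FhWey-ES and 33 with FhWild-ES (medians 0.25 and 0.21), and 0 in the difference. Of 170 genes read through another shared-sequence probe, 90 were called higher with FhWey-ES and 3 with FhWild-ES (medians 0.20 and -0.0080), and 45 in the difference.

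Markers of several cell types gave signal in the untreated macrophages. Above background in Cy3 on all 8 arrays were 10 of 19 macrophage, 11 of 16 fibroblast and 13 of 14 epithelial markers. So were 5 of 18 T cell, 3 of 10 B cell, 4 of 12 endothelial, 4 of 11 neutrophil and 5 of 12 dendritic cell markers. These shares are of the markers with a probe, and a marker counted when any 1 of its probes was above background. Of all gene spots, 60.5% to 70.5% per array were well above background in Cy3. The same share over all genes was not computed, so these counts do not identify the cells. In the order above, 12, 11, 13, 10, 5, 5, 6 and 8 of the markers passed the filter on dim probes and were tested. Called higher and lower with FhWey-ES were 0 higher and 1 lower fibroblast, 1 higher and 2 lower epithelial, 2 higher and 1 lower T cell and 3 higher and 0 lower neutrophil markers. With FhWild-ES they were 1 higher and 0 lower macrophage, 0 higher and 2 lower fibroblast, 0 higher and 1 lower T cell, 1 higher and 0 lower B cell and 1 higher and 0 lower epithelial markers, and 0 of the other kinds. The macrophage marker was PTPRC, at a shared-sequence probe, and at its other probe it was not called (0.022, adjusted p = 0.81). The B cell marker was also read through a shared-sequence probe.

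Log2 ratios fell with probe G and C content on FhWey-ES replicate 3 (correlation across probes -0.304) and FhWild-ES replicate 2 (-0.217), against -0.0953 to 0.0596 on the other 6 arrays. A correction for it kept 3820 of 4246 calls with FhWey-ES, 952 of 987 with FhWild-ES and 123 of 155 in the difference.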
